A study of Homo sapiens with 4 samples.

How the data were processed

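RNA was sequenced from 4 libraries of MDA-MB-231 cells, 2 infected with a scrambled short hairpin (shSCR) and 2 with a hairpin against JARID2 (shJARID2). Total RNA was extracted with Trizol, per the labels' protocols. How RNA was selected for the libraries (poly(A) capture or removal of ribosomal RNA) and whether the libraries kept strand are not given in the sources used here. Trimmomatic, HISAT2, SAMtools and featureCounts were used, per the submitters' processing notes, which give no versions or settings in the sources used here. The genome build, the annotation, and the rules for reads with several matches or overlapping genes are likewise not given in the sources used here. Groups and replicate numbers were taken from the labels.

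The deposited values are FPKM, per the file headers, in 1 file per library with 85553 rows. Of these rows, 25133 have a gene symbol and entered the tests, and 60420 have none and were left out. Rows without a symbol held 21.4% and 21.1% of all FPKM in shSCR replicates 1 and 2, and 24.0% and 24.5% in shJARID2 replicates 1 and 2. FPKM are not counts, so the depth was read from the steps between low values. Multiplied by the exon length of the gene in GENCODE release 29, which 24205 of the named rows matched, low values fell on whole multiples of 1 read. Of values up to 20 reads, 95.8% to 96.3% per library lay within 0.05 of a whole number. This gave depths of about 15500000, 16200000, 13000000 and 12800000 reads for shSCR replicates 1 and 2 and shJARID2 replicates 1 and 2. The match of lengths is also the reason for taking coordinates, GC content, gene types and coding lengths from GENCODE release 29 on GRCh38.

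A test on counts had been chosen before the data were examined, with limma on log2 values as the choice for FPKM, and since the files hold FPKM the latter was used. Rows with a symbol and a mean of at least 1 FPKM over the 4 libraries (12455) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and group as the only term. The 2 residual degrees of freedom were joined by 2.36 from the prior. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Between replicates, the chi-square of the recovered reads per degree of freedom was 3.13 in shSCR and 3.60 in shJARID2, so replicates differed by more than sampling noise.

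In total 39 gene lists were fixed before the data were examined, and 1097 of their 1147 entries were found, 27 of them under another symbol. The 34 lists with at least 5 tested members were compared with all other tested genes by camera (inter-gene correlation of 0.01), and with an estimated correlation and fry beside it. With an estimated correlation, camera has only the 2 residual degrees of freedom. It could therefore hardly call any list, and a list that it did not call is not evidence against that list. Counts per list refer to tested members only, for example 12 of 35 epithelial genes found. Named genes followed a rule fixed at the same time: JARID2; the 12 largest rises and the 12 largest falls among called genes with a mean FPKM of at least 5 and separate groups, leaving out pseudogenes and genes with clone or locus names; up to 4 called genes per list with the largest change; and EZH2, EED, SUZ12, LEPR, STAT3, CHD4, MTA1 and HDAC1. The rule had been written for CPM, in whose place FPKM was used. Genes outside this rule are said to be chosen after their values were seen.

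Transcript GC content of a gene was the median of the GC contents of its annotated transcripts. After fold changes were seen to follow it, a GC correction was added. In each library, deviations of log2(FPKM + 1) from the gene's mean were smoothed on GC content with loess (span 0.3, degree 2) and the smooth was subtracted, for the 12039 genes (96.7%) with a value. Genes with 6 or more annotated pseudogene copies, counted by symbol, were treated as uncertain, as were genes with 10% or more of their exon bases covered by exons of other genes. The 10% was chosen after seeing the data.

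The steps were tested on simulated reads drawn for the 12039 genes, with changes of 2-fold and 4-fold in a set of genes. Without a GC trend, limma recovered 84% of the 2-fold and 97% of the 4-fold changes and called 15 unchanged genes. With a GC trend of the observed slope added, it called 6851 unchanged genes (57.9%) without the correction and 17 (0.144%) with it, which recovered 78% and 92%. The simulated trend was linear and lay only in shJARID2, dispersion was the same for all genes, and changes were unrelated to GC content. In the data replicates also followed GC content, so these rates may be better than the real ones.

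Alternatives were other scalings, filters and pseudocounts, limma-voom on the recovered reads, a term for the replicate number, each library left out, and the GC corrections. Intervals of medians and of differences in shares came from 10000 bootstrap draws of genes at 95%. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.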

Results

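Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established human breast cancer cell line, after infection with lentivirus. The virus carried either a scrambled short hairpin (shSCR, the control) or a hairpin against JARID2 (shJARID2). JARID2 is a DNA-binding accessory subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Each group had 2 libraries. The deposited values were FPKM (fragments per kilobase of gene, scaled to the fragments of the library) for 85553 rows, of which 25133 had a gene symbol. The FPKM steps gave about 15500000 and 16200000 counted reads in shSCR replicates 1 and 2. The corresponding depths were about 13000000 and 12800000 in shJARID2 replicates 1 and 2. Values are given as mean FPKM ± SD with n = 2 libraries per group. Changes are log2 fold changes of shJARID2 against shSCR on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

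JARID2 transcript was lower in both knockdown libraries. The gene (ID 3720) lies on chromosome 6 from 15246296 to 15522040 on the + strand of GRCh38. JARID2 measured 10.8 ± 0.0611 FPKM in shSCR and 3.89 ± 0.0222 in shJARID2, a ratio of 0.360. Its FPKM corresponded to 1003 and 1056 reads in the shSCR libraries and to 302 and 301 in the shJARID2 libraries. The log2 fold change was -1.27 (SE 0.059, adjusted p = 0.0014, limma with Benjamini-Hochberg adjustment).

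The comparison of shJARID2 with shSCR asked which transcripts changed when JARID2 was depleted. The gene with the highest expression among the leading rises was S100A6, a calcium-binding protein gene, which went from 333 ± 52.7 to 1374 ± 173 FPKM. Among the steepest falls were those of FTH1, which encodes the ferritin heavy chain, and of replication-dependent histone genes such as HIST2H2AC, which went from 359 ± 23.2 to 61.4 ± 0.491 FPKM. SLC16A3, a lactate exporter, and TNFRSF12A, the TWEAK receptor, fell by 2.21 and 2.16 on the log2 scale. Of 12455 genes tested, 3493 were higher and 3941 lower in shJARID2 (adjusted p below 0.05, limma). A fitted change of 2-fold or more was seen for 352 of the higher and 772 of the lower genes. Without shSCR replicate 2, 2168 were higher and 2462 lower.

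Fold changes followed the GC content of transcripts. In the tenth of protein-coding genes with the lowest GC content (median 38.3%) the median log2 fold change was 0.47, and in the tenth with the highest (median 63.9%) it was -0.80. Across 10430 protein-coding genes Spearman's rho was -0.72, and genes are not independent replicates. Differences between the 2 libraries of a group also followed GC content, with rho of 0.35 in shSCR and 0.37 in shJARID2 (replicate 2 minus 1). When this trend was removed from each library, a step chosen after seeing the data, 2737 genes were higher and 2582 lower among 12039 with a GC value. By 2-fold or more, 218 were higher and 226 lower. Of the 7287 calls that could be compared, 3787 were kept in the same direction and 249 were called in the opposite direction. GC-corrected log2 fold changes are given beside the measured ones, and for JARID2 the value was -1.15.

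**Figure D1:**
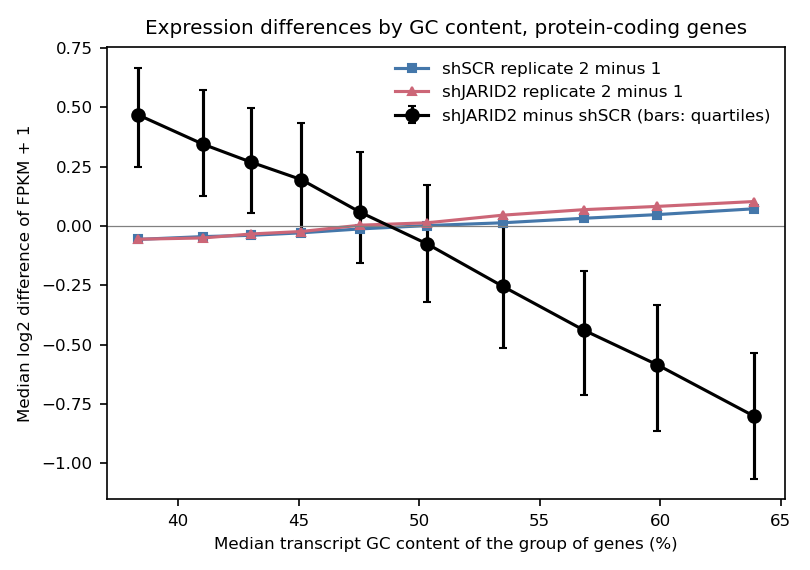
Median log2 differences of FPKM + 1 (y axis) against the median transcript GC content in % (x axis) for 10 equal groups of protein-coding genes. Black circles compare shJARID2 with shSCR, with bars from the lower to the upper quartile, and fall from 0.47 to -0.80; blue squares and red triangles give replicate 2 minus replicate 1 within shSCR and within shJARID2.

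Among called genes with a mean FPKM of 5 or more, leaving out pseudogenes and genes with clone or locus names, the largest rise was in CHAC2, which degrades glutathione, from 1.26 ± 0.265 to 10.6 ± 3.36 FPKM (2.33, GC-corrected 1.87). BRK1, a subunit of the actin-regulating WAVE complex, rose from 4.81 ± 0.0693 to 28.1 ± 5.39 FPKM (2.31, GC-corrected 2.23). S100A6 rose by 2.04 (GC-corrected 2.65) and CKS2, which binds cyclin-dependent kinases, by 1.83 (GC-corrected 1.52). NDUFB1, a subunit of respiratory complex I, rose by 2.02 (GC-corrected 1.97), MZT1 of the gamma-tubulin ring complex by 2.09 (GC-corrected 1.48), and COPS9 of the COP9 signalosome by 1.96 (GC-corrected 2.42). VKORC1, which recycles vitamin K, rose by 2.11 (GC-corrected 2.63), TMEM256 by 1.82 (GC-corrected 2.10) and TXNDC17 by 1.82 (GC-corrected 1.59). RPS29 (1.86, GC-corrected 1.96) and SNRPG (1.81, GC-corrected 1.46) completed the 12 largest rises, but have 32 and 20 annotated pseudogene copies, so reads may have been shared and their calls are uncertain. All 12 remained higher after GC correction. Their longest coding sequences ran from 225 to 756 bases (median 301.5), and those of the 12 largest falls from 207 to 1395 bases (median 390), against a median of 1458 over protein-coding genes. Exons of other genes cover 74.5% of the annotated exons of VKORC1, 36.9% of those of TXNDC17 and 29.8% of those of TMEM256. The use of strand in the counting is not given, so these 3 calls are uncertain too.

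Chosen in the same way, the 12 largest falls held 7 replication-dependent histone genes. FTH1 fell from 65.9 ± 23.3 to 5.07 ± 0.0945 FPKM (-3.42, GC-corrected -3.17). FTH1 has 25 annotated pseudogene copies and overlaps other genes over 62.4% of its exon bases, so this call is uncertain. YBX1, an RNA-binding protein gene with 10 such copies, fell by 2.29 (GC-corrected -1.97) and is uncertain for the same reason. HIST1H2AJ (-3.13 and -2.41), HIST2H2AB (-3.12 and -2.38), HIST1H3H (-2.69 and -2.68), HIST1H2AH (-2.67 and -1.98), HIST2H2AC (-2.52 and -1.79), HIST1H2AG (-2.18 and -2.30) and HIST1H2AB (-2.09 and -1.49) were the histone genes, with log2 fold changes and GC-corrected values in parentheses. COX8A, a subunit of cytochrome c oxidase, went from 19.9 ± 4.50 to 3.37 ± 0.406 FPKM (-2.24, GC-corrected -1.71), with 34.5% of its exon bases shared with other genes. SLC16A3 (GC-corrected -1.36) and TNFRSF12A (GC-corrected -1.37) completed the 12. All 12 remained lower after GC correction. Reads of the 7 histone genes may have been shared with other histone genes, so their calls are uncertain too.

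**Figure D2:**
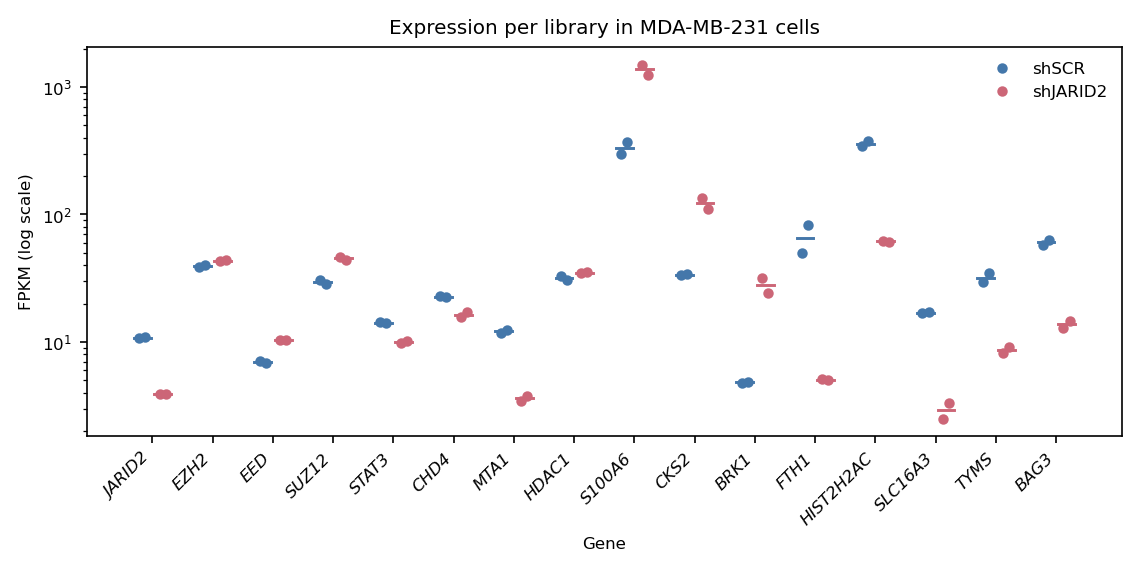
FPKM on a log scale (y axis) for 16 named genes (x axis), with a point per library and a line at the mean of each group of 2 libraries (blue shSCR, red shJARID2). JARID2 lies at 10.8 in shSCR and 3.89 in shJARID2, while EZH2 lies at 39.4 and 43.5.

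PRC2 and its partners moved in different directions. EZH2, the catalytic subunit, measured 39.4 ± 1.15 FPKM in shSCR and 43.5 ± 1.02 in shJARID2, a difference that did not pass the test (log2 fold change 0.14, adjusted p = 0.054, limma). Its GC-corrected value was -0.057. It passed under 2 other scalings of the libraries (0.17 and 0.16), with limma-voom on recovered reads (0.16) and with the replicate number as a block (0.14). EED rose by 0.52 and SUZ12 by 0.61, and the GC-corrected values were 0.055 and 0.20. Of 12 PRC2 subunits tested, 7 rose and 2 fell (8 and 2 when adjusted over the list alone, and 4 and 1 after GC correction). AEBP2 (0.85, GC-corrected 0.53) and MTF2 (0.72, GC-corrected 0.40) were among the rises. EPOP fell (-0.90), a call that ended after GC correction (-0.12), as did that of EED. Among 21 PRC1 subunits, 7 rose and 10 fell (7 and 11 adjusted over the list alone, and 4 and 5 after GC correction). BMI1 rose (1.19, GC-corrected 0.83), while CBX2 (-1.37, GC-corrected -0.63), CBX6 (-1.15, GC-corrected -0.56) and PCGF2 (-0.92) fell. The call of PCGF2 was lost after GC correction (-0.40) and without shSCR replicate 2, and exons of other genes cover 45.7% of its own.

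More subunits of the NuRD deacetylase complex fell than rose, but the list was not called (camera adjusted p = 0.105 as measured, 0.066 GC-corrected and from 0.020 to 0.16 over 13 alternatives). Of 14 tested, 2 rose and 8 fell, the same numbers when adjusted over the list alone, and 3 rose and 10 fell after GC correction. MTA1 went from 12.1 ± 0.409 to 3.61 ± 0.210 FPKM (-1.51, GC-corrected -0.84) and the helicase CHD4 from 22.6 ± 0.404 to 16.4 ± 1.04 FPKM (-0.44, GC-corrected -0.34). Exons of other genes cover 53.5% of those of CHD4. CHD3 (-0.98, GC-corrected -0.59) and GATAD2A (-0.78, GC-corrected -0.35) fell and HDAC2 rose (0.73, GC-corrected 0.42). HDAC1 did not pass the test (0.14, adjusted p = 0.089, limma), although it did after GC correction (0.26), with median-ratio scaling and with limma-voom. Of 19 JmjC-domain histone demethylases, 8 fell and 11 did not pass (7 lower adjusted over the list alone, and 9 lower after GC correction). PHF2 (-0.74, GC-corrected -0.46) and KDM5C (-0.68, GC-corrected -0.20) were lower under both measures. The calls of KDM4B (-0.88, GC-corrected -0.23) and KDM6B (-0.84, GC-corrected -0.21) ended with the correction.

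None of the 27 HOX cluster genes found in the files, classical Polycomb targets, reached a mean of 1 FPKM, so none passed the filter for testing. Without that filter the list was not called (camera adjusted p = 0.31). A value below the filter need not mean low expression, since COX5B and NDUFA8 of the respiratory chain were at most 0.107 and 0.0925 FPKM. HOXD1, singled out after its values were seen, was at 0.817 and 0.876 FPKM in shSCR and 0.117 and 0.356 in shJARID2. Of 49 other developmental regulators often marked by PRC2 that were found, only 15 passed the filter. Of these 15, 2 rose and 8 fell (2 and 9 adjusted over the list alone, and 2 and 3 after GC correction). BMP4, a secreted growth factor, rose from 44.7 ± 1.39 to 90.8 ± 4.77 FPKM (1.01, GC-corrected 1.28), and GLI2, a Hedgehog pathway transcription factor, fell (-1.83, GC-corrected -1.14). The falls of SIX2 (-1.13, GC-corrected -0.44) and IRX3 (-1.0, GC-corrected -0.22) did not pass after GC correction, and that of SIX2 was lost without shSCR replicate 1.

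Genes of leptin, IL-6 family and STAT3 signalling moved both ways, with 6 of 23 higher and 11 lower (the same adjusted over the list alone, and 8 and 5 after GC correction). STAT3 fell from 14.2 ± 0.00135 to 10.0 ± 0.349 FPKM (-0.47, GC-corrected -0.35). The leptin receptor gene LEPR lay below the filter, at 0.636 and 0.853 FPKM in shSCR and 1.15 and 1.20 in shJARID2, and was not tested in the main fit. It entered the alternatives with no filter and with 1 FPKM required in 2 libraries, whose results for it are not given here. BCL3 (-1.58, GC-corrected -0.72) and IL11 (-1.18, GC-corrected -0.43) fell and LIFR rose (0.75, GC-corrected 0.41). CEBPB was lower as measured (-0.79) but at 0.078 after GC correction, where it did not pass.

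Epithelial and mesenchymal genes both split. Of 12 epithelial genes, 3 rose and 6 fell (3 and 4 after GC correction). KRT19, a keratin, fell (-1.98, GC-corrected -1.39) with the protease inhibitor SPINT2 (-1.29, GC-corrected -0.83) and EVPL (-1.17, GC-corrected -0.35), whereas the adhesion molecule EPCAM rose (1.18, GC-corrected 0.99). Of 17 mesenchymal genes, 4 rose and 7 fell (4 and 5 after GC correction). SNAI2, an EMT transcription factor, rose (1.02, GC-corrected 0.72) with S100A4 (0.76, GC-corrected 0.95), and the receptor tyrosine kinase AXL fell (-1.19, GC-corrected -0.62). WNT5B fell as measured (-0.56) but was at 0.047 after GC correction. Adjusted over the list alone, 3 epithelial genes were higher and 6 lower, and 4 mesenchymal genes were higher and 8 lower. The call of S100A4 was lost without shSCR replicate 2, and that of WNT5B without any of shSCR replicate 1, shSCR replicate 2 and shJARID2 replicate 1, with the replicate number as a block and with no filter on low values.

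Matrix and adhesion genes were more often lower as measured. 5 of 26 collagens, laminins and matrix glycoproteins rose and 16 fell, but 9 rose and 5 fell after GC correction. AGRN (-1.04, GC-corrected -0.18) and LAMA5 (-1.0, GC-corrected -0.17) shrank with the correction, and the calls of COL18A1 (-1.17, GC-corrected -0.27) and COL6A1 (-0.91, GC-corrected -0.14) ended. Integrin and focal adhesion genes gave 9 rises and 15 falls among 30 (7 and 11 after GC correction). CAV2, a caveolae component, rose (1.33, GC-corrected 1.05), and ACTN4 (-1.27, GC-corrected -0.73), BCAR1 (-1.25, GC-corrected -0.39) and ITGB4 (-1.21, GC-corrected -0.47) fell. Among 22 matrix proteases and inhibitors, 5 rose and 11 fell (4 and 6 after GC correction). PLAU, the urokinase gene, rose (0.82, GC-corrected 1.09) while its receptor gene PLAUR (-1.16, GC-corrected -0.78) and the membrane protease gene MMP14 (-1.35, GC-corrected -0.79) fell. ADAM8 lost its call after GC correction (-0.91, GC-corrected -0.068). Adjusted over the list alone, 5 matrix genes rose and 18 fell, 9 adhesion genes rose and 15 fell, and 5 protease genes rose and 12 fell.

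Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, almost all fell. Of 19 tested, 17 fell and only HIST1H4I rose, the same numbers when adjusted over the list alone. The median log2 fold change was -1.40 (GC-corrected -1.05, with 2 higher and 14 lower). The list was called lower (camera adjusted p = 1.4e-05, from 2.8e-07 to 5.5e-05 over 13 alternatives, and adjusted p = 0.52 with an estimated correlation). HIST1H4I was singled out after its values were seen, and went from 15.2 ± 2.47 to 32.7 ± 0.713 FPKM (1.07, GC-corrected 0.94). The count of pseudogene copies by symbol does not cover other histone genes of similar sequence. The rules for reads with several matches are not given, so reads may have been shared and calls of histone genes are uncertain.

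Cell cycle genes moved both ways. Of 38 mitotic genes, 18 rose and 10 fell (20 and 10 adjusted over the list alone), which became 13 and 16 after GC correction, with the median turning from 0.14 to -0.11. CKS2 and the checkpoint gene MAD2L1 (0.88, GC-corrected 0.50) rose, and CDC20 (-1.20, GC-corrected -0.75) and the kinase gene PLK1 (-1.18, GC-corrected -0.73) fell. DNA replication and E2F genes gave 16 rises and 22 falls among 47 (16 and 24 adjusted over the list alone, and 14 and 12 after GC correction). TYMS, which makes thymidylate, fell from 32.0 ± 3.55 to 8.66 ± 0.670 FPKM (-1.77, GC-corrected -1.58), with 46.6% of its exon bases shared with other genes. CDT1 (-1.32, GC-corrected -0.48) and CCND1, which encodes cyclin D1 (-1.17, GC-corrected -0.40), fell and RPA3 rose (1.32, GC-corrected 1.12). Among 25 p53 targets and CDK inhibitors, 8 rose and 9 fell (8 and 10 adjusted over the list alone, and 7 and 3 after GC correction). CDKN1A fell (-1.20, GC-corrected -0.63) and GADD45A rose (0.85, GC-corrected 1.29). The falls of GADD45B (-1.06, GC-corrected -0.47) and BAX (-0.91, GC-corrected -0.28) passed neither after GC correction nor without shSCR replicate 2. Apoptosis regulators gave 9 rises and 2 falls among 20, the same adjusted over the list alone, and 6 and 4 after GC correction. The inhibitors BIRC2 (1.08, GC-corrected 0.79) and XIAP (0.89, GC-corrected 0.72) rose and the death effector gene BAK1 fell (-0.97, GC-corrected -0.43).

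Of 26 interferon-stimulated genes, 4 rose and 7 fell as measured (3 and 7 adjusted over the list alone), and 1 was higher and 10 lower after GC correction. The list was not called as measured (camera adjusted p = 0.56) and was called lower after GC correction (camera adjusted p = 0.023, from 0.014 to 0.61 over 13 alternatives, and adjusted p = 0.65 with an estimated correlation). OAS3 (-1.13, GC-corrected -0.76) and OASL (-1.10, GC-corrected -0.76) were lower, whereas ISG15 (-0.99, GC-corrected -0.20) and IRF7 (-0.88, GC-corrected 0.031) lost their calls with the correction. Of 13 antigen presentation genes, 1 rose and 5 fell (1 and 4 adjusted over the list alone, and 4 and 1 after GC correction). The peptide transporter gene TAP1 fell (-1.27, GC-corrected -0.99). HLA-E was called lower as measured (-0.49) and higher after GC correction (0.32). PSMB10 (-1.08, GC-corrected -0.39) and CD274, which encodes PD-L1 (0.49, GC-corrected 0.20), lost their calls with the correction, and that of CD274 was also lost without shSCR replicate 2 or shJARID2 replicate 2.

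NF-kB targets, cytokines and chemokines gave 5 rises and 9 falls among 22, the same adjusted over the list alone, and 3 and 7 after GC correction. ICAM1, an adhesion molecule (-1.27, GC-corrected -0.73), and NFKB2 (-1.13, GC-corrected -0.43) fell, and RELB was lower only as measured (-0.81, GC-corrected 0.014). For TGF-beta and SMAD targets, 9 of 25 rose and 7 fell, the same adjusted over the list alone, and 8 and 4 after GC correction. TGFB1 fell (-1.5, GC-corrected -0.99) while SKI (-0.70, GC-corrected 0.011) and LTBP3 (-0.66, GC-corrected 0.15) were lower only as measured, and LTBP3 lost its call without shSCR replicate 2 or shJARID2 replicate 1. YAP and TEAD targets split evenly, with 9 of 26 higher and 10 lower (10 and 10 adjusted over the list alone, and 10 and 9 after GC correction). ANKRD1 rose (0.84, GC-corrected 0.58) and FJX1 fell (-1.04, GC-corrected -0.50).

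Of 35 hypoxia and glycolysis genes tested, 23 fell and 4 rose, the same adjusted over the list alone, and 18 fell and 3 rose after GC correction. The list was called lower (camera adjusted p = 0.0028 as measured, 0.0035 GC-corrected and from 5.8e-05 to 0.009 over 13 alternatives, with adjusted p = 0.52 and 0.65 with an estimated correlation). The largest falls were in SLC16A3, in DDIT4, an mTORC1 inhibitor (-1.5, GC-corrected -0.68), in NDRG1 (-1.26, GC-corrected -0.78) and in the aldolase gene ALDOA. ALDOA stands on 2 records of the files, both counted here, with log2 fold changes of -1.70 and -1.01 and no GC-corrected value. Exons of other genes cover 53.5% of those of ALDOA and 41.2% of those of DDIT4.

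Lipid genes leaned lower as measured. Cholesterol biosynthesis gave 4 rises and 15 falls among 24 (6 and 15 adjusted over the list alone, and 4 and 10 after GC correction). The sterol transcription factor gene SREBF2 (-1.22, GC-corrected -0.77), MVD (-1.35, GC-corrected -0.57) and TM7SF2 (-1.0, GC-corrected -0.27) fell. CYP51A1 fell too (-1.38, GC-corrected -1.71), with exons of other genes over 83.2% of its own. Fatty acid and lipid metabolism gave 6 rises and 20 falls among 35, the same adjusted over the list alone, and 5 and 13 after GC correction. FADS3 (-1.34, GC-corrected -0.70), PLIN3 (-1.21, GC-corrected -0.64) and the fatty acid synthase gene FASN (-1.13, GC-corrected -0.29) fell, and PNPLA2 lost its call with the correction (-0.88, GC-corrected -0.076).

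Of 14 heat shock and proteostasis genes, 2 rose and 8 fell, the same adjusted over the list alone, and 2 and 10 after GC correction. The list did not pass as measured (camera adjusted p = 0.074) and passed after GC correction (camera adjusted p = 0.016, from 0.011 to 0.11 over 13 alternatives, and adjusted p = 0.65 with an estimated correlation). BAG3, an HSP70 co-chaperone, fell from 60.4 ± 3.83 to 13.7 ± 1.37 FPKM (-2.06, GC-corrected -1.5), with HSPA1B (-1.06, GC-corrected -0.53) and SQSTM1 (-0.89, GC-corrected -0.25), while DNAJB4 rose (1.37, GC-corrected 1.05). The unfolded protein and ATF4 response gave 6 rises and 11 falls among 24, the same adjusted over the list alone, and 6 and 4 after GC correction. The endoplasmic reticulum chaperone gene HSPA5 fell from 102 ± 0.527 to 51.0 ± 0.0455 FPKM (-0.99, GC-corrected -1.15) and CALR fell (-1.09, GC-corrected -0.74). SLC7A11, a cystine transporter, rose (1.12, GC-corrected 0.72), and CHAC1 lost its call with the correction (-0.90, GC-corrected -0.20).

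Nuclear genes of the respiratory chain gave 12 rises and 9 falls among 31 (13 and 9 adjusted over the list alone, and 14 and 5 after GC correction). NDUFA4 (1.19, GC-corrected 0.82), NDUFB5 (1.14, GC-corrected 0.78), COX6A1 (1.0, GC-corrected 1.13) and COX5A (0.94, GC-corrected 1.05) rose. Only 2 mitochondrially encoded genes were tested and neither passed, in all genes or adjusted over the list alone: MT-ND3 was at 0.24 (adjusted p = 0.4, limma, GC-corrected -0.11) and MT-CO1 at -0.40 (adjusted p = 0.055, limma, GC-corrected -0.56, which passed). They rest on 16 to 24 reads per library for MT-ND3 and 21 to 50 for MT-CO1, so they are no measure of mitochondrial expression. Ribosomal protein genes were more often lower, with 10 of 48 higher and 25 lower, the same adjusted over the list alone, and 10 and 19 after GC correction. The list was called lower (camera adjusted p = 0.041 as measured, 0.028 GC-corrected and from 0.002 to 0.048 over 13 alternatives, with adjusted p = 0.52 and 0.65 with an estimated correlation). RPS9 (-2.05, GC-corrected -1.48), RPL8 (-1.93, GC-corrected -1.28), RPL19 (-1.28, GC-corrected -1.02) and RPL35 (-1.21, GC-corrected -0.72) fell. RPL19 and RPL35 have 8 pseudogene copies each, so their reads may have been shared. RPLP2, RPL29 and RPS27 lay below the filter, at 0.316 to 1.42, 0.245 to 1.07 and 0.679 to 1.04 FPKM over the libraries. Whether reads of ribosomal protein genes were counted in full is not known, so the call of the list is uncertain.

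Of 6 stem cell factors, 3 rose and 3 fell, the same adjusted over the list alone, and 2 and 2 after GC correction. BMI1 was among the rises, and ITGA6 (-0.91, GC-corrected -1.22) and KLF4 (-0.74, GC-corrected -0.42) fell. MYC was called lower as measured (-0.26) and higher after GC correction (0.27), and its measured call was lost without shSCR replicate 2. Notch pathway genes gave 1 rise and 9 falls among 13 (1 and 10 adjusted over the list alone, and 1 and 2 after GC correction). RBPJ rose (0.66, GC-corrected 0.35) and NOTCH1 fell (-0.95, GC-corrected -0.16), while NRARP lost its call with the correction (-1.32, GC-corrected -0.40) and RFNG was lower only as measured (-0.75, GC-corrected 0.047). Wnt pathway genes gave 4 rises and 13 falls among 24, the same adjusted over the list alone, and 7 of each after GC correction. SP5 (-1.57, GC-corrected -0.41) and TCF7L1 (-1.15, GC-corrected -0.94) fell and the secreted inhibitor gene DKK1 rose (0.73, GC-corrected 0.44).

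ERK output and immediate early genes gave 3 rises and 15 falls among 24 (5 and 15 adjusted over the list alone), but 8 and 10 after GC correction. KLF2 (-2.05, GC-corrected -1.15), ETV4 (-1.72, GC-corrected -1.14), EGR1 (-1.49, GC-corrected -1.14) and the ERK phosphatase gene DUSP4 (-1.43, GC-corrected -1.16) were lower under both measures, although the call of EGR1 was lost without shSCR replicate 2. Of 11 angiogenic factors, 4 rose and 3 fell, the same adjusted over the list alone, and 3 of each after GC correction. VEGFC rose (0.53, GC-corrected 0.42) and VEGFA (-1.02, GC-corrected -0.56) and EPHB4 (-1.06, GC-corrected -0.39) fell. EDN1 rose as measured (0.47, GC-corrected 0.28), a call lost after GC correction and without shSCR replicate 2.

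Markers of other cell types were mostly below the filter. COX5B and NDUFA8 of the respiratory chain were below it too, so this is weak evidence that the markers were absent. Of 17 luminal breast genes found, 6 were tested and 5 fell, the same adjusted over the list alone, and 3 after GC correction. This list was called lower (camera adjusted p = 0.041, from 0.035 to 0.1 over 13 alternatives, and adjusted p = 0.52 with an estimated correlation) and was not called after GC correction (camera adjusted p = 0.095). KRT19, KRT8 (-1.06, GC-corrected -0.55), MLPH (-0.95, GC-corrected -0.53) and KRT18 (-0.77, GC-corrected -0.33, no longer called) were its leading members, and KRT8 and KRT18 have 50 and 67 pseudogene copies. The only blood cell gene tested, LCP1, rose (1.0, GC-corrected 0.82), and the only genes tested of fibroblasts, MFAP4 (-0.79, GC-corrected -0.37) and FBLN1 (-0.63, GC-corrected -0.046), were lower as measured. GAL was the only tested gene of the HEK293 line, often used to package virus, and was lower as measured (-0.78, GC-corrected 0.093). All 4 of these calls stood when adjusted over the list alone, while those of MFAP4, FBLN1 and GAL ended after GC correction. Without shSCR replicate 2, the calls of KRT18, MFAP4 and GAL were lost, and that of MFAP4 was also lost without shSCR replicate 1.

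**Figure D3:**
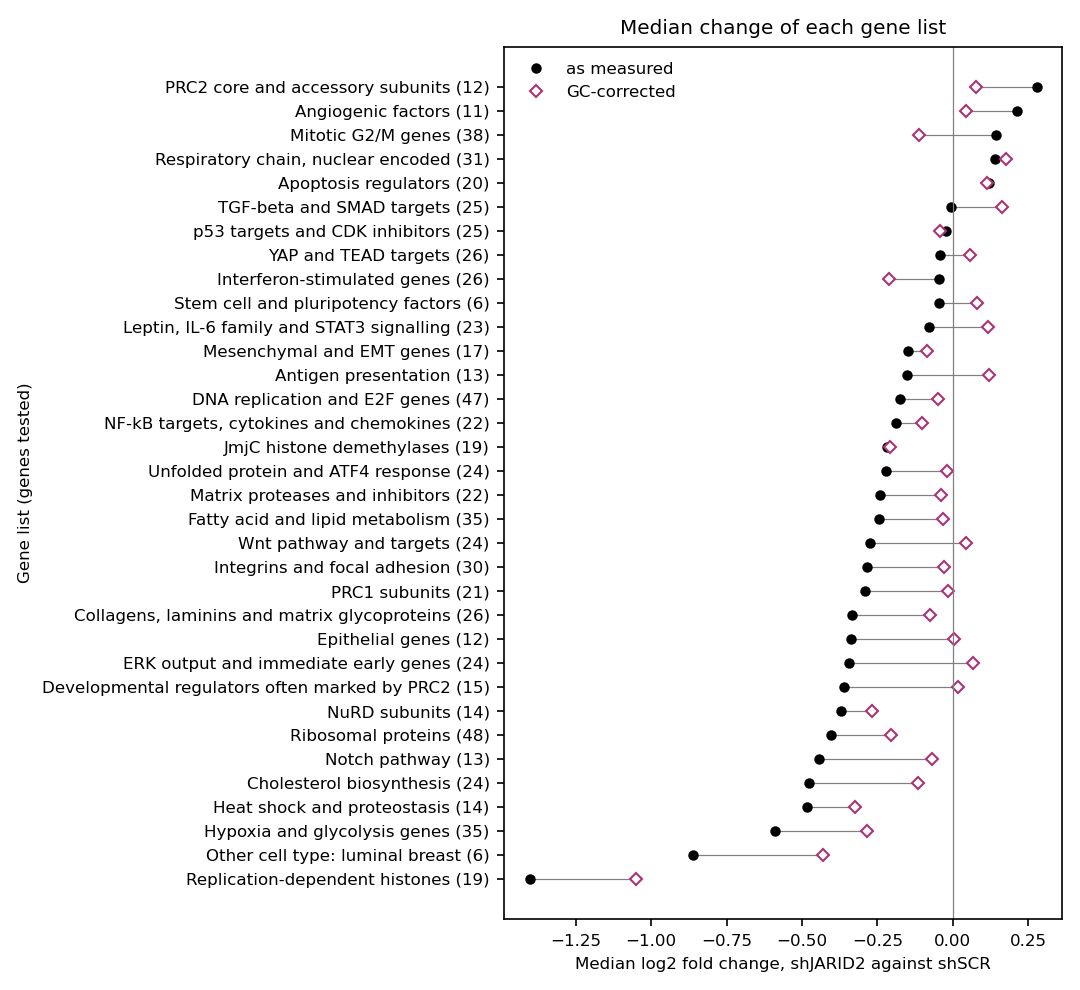
Median log2 fold change of shJARID2 against shSCR (x axis) for each of the 34 gene lists with 5 or more genes tested (y axis, number tested in parentheses), as measured (black circles) and after GC correction (open diamonds). Replication-dependent histones lie lowest at -1.40 and -1.05.

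Over the 34 lists tested with camera, none was called higher and 4 were called lower: histones, hypoxia and glycolysis, ribosomal proteins and luminal breast genes. None of the 4 held with an estimated correlation (adjusted p = 0.52 for each). After GC correction, 6 were called lower (histones, hypoxia and glycolysis, heat shock, interferon-stimulated genes, JmjC demethylases and ribosomal proteins), and none of these held with an estimated correlation (adjusted p = 0.65 for each). At an unadjusted p below 0.05, camera gave 0 lists higher and 14 lower. The directional test fry, which asks whether a list moves on balance without comparing it with other genes, called 4 lists higher and 27 lower. Medians and tests as measured differed in sign for 4 lists. The medians of p53 targets (-0.023), TGF-beta targets (-0.0047) and stem cell factors (-0.046) lay below 0 while camera placed them higher, and the median of angiogenic factors (0.21) lay above 0 while its mean (-0.027) and fry pointed lower.

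Several of these genes rest on few reads or on shared exons. SIX2, IRX3, GADD45B, CHAC1, MT-ND3 and NRARP had fewer than 20 reads in at least 1 library, as did HIST1H2AJ among the leading falls. Exons of other genes cover 31.1% of those of PLAU, 34.8% of those of PSMB10 and 36.5% of those of HSPA1B. They cover from 10.3% to 23.6% of those of ICAM1, BMI1, SQSTM1, RFNG, PLIN3, COL18A1, KRT18, ACTN4, COX6A1, PLK1, CEBPB, PNPLA2 and CCND1. Calls of all genes named with few reads or shared exons are uncertain.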

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

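All tests in this part were chosen only after the result was seen. Rows of the files without a gene symbol, which none of the comparisons used, held a larger share of all FPKM in shJARID2 than in the control libraries: 24.2% ± 0.334 against 21.2% ± 0.234 (mean ± SD, n = 2 libraries per group). Of the 10599 such rows with a mean of at least 1 FPKM, 4047 were higher in both shJARID2 libraries than in both shSCR libraries and 2589 were lower in both.

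Fold changes followed transcript GC content, from a median of 0.47 in the tenth of protein-coding genes with the lowest GC content to -0.80 in the highest. A difference in depth with noise near the floor is argued against by the most abundant of 4 equal groups of protein-coding genes (2608), in which rho was -0.70. A GC bias that differs between libraries can make replicates differ along GC content too, and they did, with rho of 0.345 in shSCR and 0.369 in shJARID2. Their decile medians moved only from -0.06 to 0.10, far less than those between the groups. A bias shared by the libraries of a group would leave replicates alike, so replicates cannot decide this question. The trend between groups may be wholly or partly technical. An effect of JARID2 knockdown on GC-rich genes stays open and untested, since group and library preparation cannot be separated here.

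Replication-dependent histone genes fell, and sharing of reads among them was not tested. The GC trend as the whole cause is argued against by their GC-corrected median of -1.05 (95% interval -1.49 to -0.34, n = 19 genes). That interval covers the spread among genes and not between libraries. How well the smooth over all genes fits histone genes was not tested. A lower yield of RNA without a poly(A) tail stays open: the GC-corrected median of 428 snRNA and snoRNA genes was -0.10 (-0.22 to 0.0079), and many of these genes lie in introns whose reads they could hold. Fewer cells in S phase also stays open, with a GC-corrected median of DNA replication genes of -0.048 (-0.20 to 0.08, n = 47). Knockdown of JARID2 itself is a further open explanation that was not tested.

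Genes with short coding sequences changed most: after GC correction, 4.37% of the protein-coding genes in the shortest of 5 equal groups were higher by 2-fold or more against 0.144% in the longest, and 2.85% against 0.384% were lower. Counting noise in genes with few reads is argued against by the genes with at least 500 reads in every library, again in 5 groups. Among these, 2.55% of the shortest and 0% of the longest were higher by 2-fold or more, a difference of 2.55 percentage points (95% interval 1.63 to 3.57). For the falls it was 1.12% against 0.205%, a difference of 0.918 percentage points (0.203 to 1.63). At equal reads a longer gene has a lower FPKM, so the log2(FPKM + 1) scale shrinks its change more. Part of these differences may come from the scale, which was not tested. Uneven recovery of short transcripts between libraries may contribute, because the GC-corrected difference between the shJARID2 replicates followed coding length with rho of 0.177 (0.00722 between the shSCR replicates). With at least 500 reads, these were 0.286 and 0.0567, and rho between the groups was -0.320. An effect of the knockdown stays open and was not tested.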

How the results depend on the processing

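The GC-corrected and the GC- and length-corrected alternatives were chosen after seeing the data. The length used was that of all annotated exons of a gene, not its coding length. The pattern along coding length was therefore not itself corrected. The others were chosen before the data were examined, apart from the form they took for FPKM. Of the planned fits on counts, limma-voom was run on the recovered reads, and the others and their size factors were not run because the files hold FPKM. In place of those size factors, the libraries were scaled by median ratios or to the same total over named genes.

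JARID2 kept its direction and its call under every alternative, from -1.45 with limma-voom to -1.12 with the GC- and length-corrected fit, and from -1.28 to -1.27 with 1 library left out. With 1 library left out, the genes called higher ranged from 2168 to 3068 and those lower from 2462 to 3763, and by 2-fold or more from 325 to 433 and from 684 to 980. Both lowest counts, 2168 and 2462, came without shSCR replicate 2. Leaving out a library gave 0 lists higher and 3 to 4 lower; the group left with 1 library is then assumed to vary like the other.

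A pseudocount of 0.1 gave 1258 genes lower by 2-fold or more, and limma-voom on the recovered reads gave 558 higher and 1248 lower. Both raise the fold changes of low genes by construction. The GC-corrected fit gave 2582 genes lower, and 218 higher and 226 lower by 2-fold or more, and the GC- and length-corrected fit gave 209 and 221. The higher share of calls was 47.0% as reported, 51.5% GC-corrected and 49.0% with median ratios. Camera called 10 lists lower with no filter. It called 0 with an estimated correlation, GC-corrected or not, where 2 residual degrees of freedom left little room for a call. Fry, which compares no list with other genes, called 4 higher and 27 lower.

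Of the genes named, 12 changed direction under both the GC-corrected and the GC- and length-corrected fit, and the cause was not tested beyond the correction itself. The values were, in this order, -0.057 and -0.065 for EZH2, 0.078 and 0.052 for CEBPB, 0.047 and 0.055 for WNT5B, 0.031 and 0.0045 for IRF7, 0.32 and 0.32 for HLA-E, 0.014 and 0.012 for RELB, 0.011 and 0.018 for SKI, 0.15 and 0.13 for LTBP3, -0.11 and -0.062 for MT-ND3, 0.27 and 0.28 for MYC, 0.047 and 0.054 for RFNG and 0.093 and 0.063 for GAL. Another 22 lost their call under each correction. Only HLA-E and MYC were called in the opposite direction. Without shSCR replicate 2, 14 named genes lost their call, and without the other libraries 1 to 4 did. HMOX1 lost its call without either shSCR library and with no filter, as did WNT5B. HDAC1 gained a call with median ratios, limma-voom and both corrections, EZH2 with both scalings and limma-voom, and MT-CO1 with both corrections and when 1 FPKM was required in 2 libraries.

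Over 12042 genes, r between the deviations of libraries with the same replicate number from their group means was 0.0142, although replicate 2 minus 1 followed GC content in the same direction in both groups (rho 0.345 and 0.369). With the replicate number as a block, 3380 genes were higher and 3831 lower, 377 and 787 of them by 2-fold or more, WNT5B lost its call, EZH2 gained one and no other named gene or list count changed its call.

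At about 12800000 to 16200000 reads per library, genes near 1 FPKM rest on few reads, and with 2 libraries per group the spread of a single gene is known poorly.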

Other observations

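The genes of this part were chosen after their values were seen, and were tested in the same way as the others. The metallothionein genes MT1E and MT1X, which bind zinc and copper, rose from 95.2 ± 0.295 to 234 ± 14.7 FPKM (log2 fold change 1.29, GC-corrected 1.54) and from 4.57 ± 0.590 to 10.3 ± 0.826 FPKM (1.02, GC-corrected 1.21). CYP1B1, a cytochrome P450 gene, rose by 1.25 (GC-corrected 1.64), and TGFA, which encodes a ligand of the EGF receptor, by 0.94 (GC-corrected 1.5). The CDK4/6 inhibitor gene CDKN2D rose by 0.83 (GC-corrected 1.5). The BMP target genes ID1 and ID3 were at 0.64 and 0.37 (GC-corrected 1.14 and 0.82). The TGF-beta and SMAD list, which holds them and BMP4, was not called (camera adjusted p = 0.84, and 0.33 after GC correction). In that list, SMAD6 lay below the filter, at 0.859 and 0.873 FPKM in shSCR and 0.171 and 0.410 in shJARID2. ID2 lay below it too, at 0 and 0.028 FPKM in shSCR and 0.245 and 0.177 in shJARID2. The heme oxygenase gene HMOX1 rose by 0.54 (GC-corrected 1.19), a call that was lost without either shSCR library and with no filter on low values. Exons of other genes cover 18.1% of those of MT1X and 13.0% of those of CYP1B1, so these calls are uncertain.

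The disulfide isomerase gene PDIA6 went from 14.5 ± 0.871 to 4.51 ± 0.0709 FPKM (-1.49, GC-corrected -1.65), with 25.2% of its exon bases shared with other genes. PRKCSH, a glucosidase II subunit, fell by 1.98 (GC-corrected -1.34), RRBP1 by 1.89 (GC-corrected -1.32) and the zinc transporter gene SLC39A7 by 1.69 (GC-corrected -1.35). The mitochondrial chaperone gene HSPA9 fell by 1.05 (GC-corrected -1.23) and the HSP90 co-chaperone gene AHSA1 by 1.21 (GC-corrected -1.16). CD9, a tetraspanin of the cell surface, went from 19.0 ± 1.87 to 5.63 ± 0.362 FPKM (-1.59, GC-corrected -1.59). SLBP, whose product binds the stem-loop of histone mRNAs, rose from 30.01 ± 0.262 to 52.3 ± 3.92 FPKM (0.78, GC-corrected 0.83) while those mRNAs fell. H3F3A, a histone gene whose mRNA has a poly(A) tail, fell by 1.23 (GC-corrected -1.53), a call that is uncertain since H3F3A has 6 annotated pseudogene copies.

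After GC correction, 12.5% of the 176 genes with 6 or more annotated pseudogene copies differed by 2-fold or more, against 2.24% of the 9100 genes without a copy.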
